A study of Homo sapiens with 3 samples.

How the data were processed

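Single cells of established human breast cancer cell lines were captured in droplets by inDrop, a method that tags each messenger RNA with a cell barcode and a unique molecular identifier (UMI), so that copies made by amplification are counted once. The series held 15 libraries in 3 deposited sets. The MCF7 set held untreated MCF7, MCF7 treated with KDM5-C70 and C70R, the MCF7 derivative named for its resistance to that compound. The label of its untreated library spelled the line name differently and was read as MCF7. The pMCF7 set held parental MCF7 (pMCF7) untreated and treated with fulvestrant, the fulvestrant-resistant derivative FULR with and without KDM5-C70, and SUM159 with and without KDM5-C70. The last set held BT474, T47D and ZR75, each with and without KDM5-C70 by its file names. Its label describes a mix that was not demultiplexed, while the files were separate by line and treatment. The file names were followed, and the assignment of treatment within a line could not be checked. KDM5-C70, called C70 from here on, inhibits the KDM5 histone H3K4 demethylases and was used at 10 µM. Fulvestrant, an antagonist and degrader of the estrogen receptor, was used at 1 µM. The duration of treatment was not given, and C70R and FULR carried no drug in their labels. FULR was grown in a medium that lacked phenol red and held charcoal-stripped serum, unlike the medium given for MCF7, so that resistance and medium cannot be separated in it. No medium was given for pMCF7 by that name. MCF7 and FULR are related lines.

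The deposited values were counts, that is, whole numbers of UMIs per gene and cell barcode as the authors made them, with no normalization. Bowtie 1.1.1, SAMtools 1.3.1, Trimmomatic (no version given) and the build GRCh38 were named in the submitters' processing notes. Their settings, the annotation release and the rules that selected cells and genes were not given in the sources used here. The files listed 7738 genes in the MCF7 and pMCF7 sets and 8019 in the BT474, T47D and ZR75 set, of which 7281 were shared, so a gene missing from a file is not known to be unexpressed. The lowest barcode held 1197 UMIs, so the filter of at least 1000 UMIs per barcode removed none of the 29939 barcodes. No doublet caller was run and doublets were not removed, so a barcode is not known to hold a single cell. In the pMCF7 set the barcode names carried a part number, 1 or 2, whose meaning was not stated. FULR and SUM159.C70 were uneven in it, with 19 barcodes of FULR in part 1 and 26 of SUM159.C70 in part 2. Untreated pMCF7 had 766 in part 1 and 161 in part 2. Short reads of near-identical genes cannot always be separated, which concerns KRT81, the HLA genes, the metallothioneins, the IFITM genes, FTL and HSPA1A with HSPA1B.

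UMIs were summed over the cells of each library, because cells of 1 library are not replicates. The effect of C70 was tested over the 6 line pairs (MCF7, FULR, SUM159, BT474, T47D and ZR75), with the cell line as a block, on the 7281 shared genes. edgeR 4.0.16 in R 4.3.3 was used with TMM factors, filterByExpr and the quasi-likelihood F test, with 5 residual and 7.22 prior degrees of freedom. P-values were adjusted by the method of Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. These p-values measure the spread between lines, since each line was measured once in each condition. Folds for single lines used TMM factors and a prior count of 2, and UMIs per 1e6 UMIs (CPM) in this test were over the shared genes. On simulated data with 6 pairs, the test recovered 72.7% of 66 genes changed by 0.5 on the log2 scale and 100% of the 67 changed by 1, and 5.21% of its calls were false.

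Before the data were examined, 21 gene lists were fixed, along with the comparisons, tests, thresholds and the rule for named genes. The lists were antigen presentation, basal and mesenchymal genes, cholesterol synthesis, the ERBB2 amplicon, estrogen response, G1/S and G2/M cell cycle genes, germline genes, H3K4 methyltransferases, heat shock and immediate early genes, hypoxia and glycolysis, interferon-stimulated genes, the KDM5 family, luminal genes, metallothioneins, mitochondrially encoded genes, markers of nonepithelial cells, oxidative phosphorylation, p53 targets, ribosomal proteins, and the ATF4 and unfolded protein stress response. The 16 lists with at least 5 genes in the fit were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation. Line means of each list were tested by exact sign flips over the 6 pairs, two-sided, for which the smallest possible p is 0.03125. Genes were also counted with p-values adjusted over the list alone.

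C70R against MCF7, FULR against pMCF7 and fulvestrant-treated against untreated pMCF7 had 1 library on each side, so no test between replicates was possible. Ratios of CPM over all genes of the file are given with exact conditional 95% intervals, which cover counting error only. Genes with 0 UMIs on one side are given as bounds at a floor of 3 counts. List medians took members with at least 20 CPM in either library, added 0.5 UMI before the log2 ratio, and were ranked among 10000 random lists drawn from the same 20 bins of expression. The intervals held the true ratio for 95.6% of genes in simulated data. Named genes were, by rule, the 10 largest ratios in each direction with at least 100 CPM in 1 library and 5 UMIs in the other, the 5 most abundant genes below 5 UMIs in the other library, up to 4 members of each list, and ESR1, PGR, GREB1, TFF1, KDM5A, KDM5B, KDM5C and MKI67. For C70 across lines the rule took up to 12 called genes per direction that changed the same way in every line, with an average log2 CPM of at least 5, up to 4 members of each list and the same 8 genes.

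Cell-to-cell heterogeneity was measured on cells thinned at random to 1000 UMIs, in equal numbers of cells on both sides of a comparison, over genes with a mean thinned count of at least 0.2. Overdispersion was the median over genes of the variance beyond Poisson noise, relative to the squared mean. Cell-to-cell distance was the mean over pairs of cells of 1 minus the Pearson correlation of log counts. For C70, differences per line were tested by exact sign flips. Other comparisons carry 95% ranges from 100 resamples of cells, which hold no spread between cultures. In simulated libraries of unequal depth a log2 ratio of 0.58 was recovered as 0.56 and a ratio of 0 as −0.02.

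Alternatives covered normalization (RLE, library totals, DESeq2 1.42.0), cell filters (at least 2000 UMIs, at most 20% mitochondrial UMIs, no cells above 3 times the median), thinned libraries, the model without the line block, single deposited sets, each line left out, the thinning depth (500 and 2000 UMIs), the gene minimum (0.1 and 0.5), other distances and other control libraries. Interaction tests (C70 by set and C70 by SUM159), 1 barcode part per line, heterogeneity within sets and ratios for single lines were added after the data were seen. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions were matched by symbol to GENCODE release 29 on GRCh38, and 307 of the 311 genes looked up matched 1 position.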

Results

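Transcriptomes of single cells were measured in 8 breast cancer cell lines and derivatives, untreated or treated with the KDM5 inhibitor C70 or with the estrogen receptor antagonist fulvestrant. MCF7, T47D and ZR75 are estrogen receptor positive luminal lines, BT474 is a luminal line with amplified ERBB2, and SUM159 is a mesenchymal-like line that lacks the estrogen receptor. The series title frames the question as whether KDM5B ties differences between cells of a population to resistance to therapy. Each condition was represented by 1 library, and C70 was applied to 6 lines, which served as the replicates of its effect. The MCF7 set gave 1175 cells of MCF7 (6040918 UMIs), 733 of MCF7.C70 (5208118 UMIs) and 1718 of C70R (8441037 UMIs). In the pMCF7 set there were 927 cells of pMCF7 (3243790 UMIs), 1628 of fulvestrant-treated pMCF7 (5069580 UMIs), 502 of FULR (1205483 UMIs), 1655 of FULR.C70 (5154772 UMIs), 2276 of SUM159 (10846650 UMIs) and 1676 of SUM159.C70 (5704396 UMIs). The BT474, T47D and ZR75 set held 3562 cells of BT474 (14135668 UMIs), 3132 of BT474.C70 (13122740 UMIs), 2530 of T47D (8916774 UMIs), 2427 of T47D.C70 (9096907 UMIs), 2811 of ZR75 (12745411 UMIs) and 3187 of ZR75.C70 (16014202 UMIs). Median depth ran from 2219 UMIs per cell in FULR to 6739 in MCF7.C70.

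The SUM159 and BT474 libraries carried markers of the lines they were named for. The markers given here were not used to tell T47D from ZR75, or MCF7, pMCF7, C70R and FULR from each other. SUM159 held 4877 CPM of VIM, the mesenchymal intermediate filament, and 441 CPM of the epithelial keratin KRT8. BT474 held 1650 CPM of ERBB2, against at most 127 CPM in the other lines. Mitochondrially encoded transcripts took 16.1% to 22.8% of the UMIs in the BT474, T47D and ZR75 set and 5.86% to 10.2% in the other sets, while ribosomal protein transcripts took 9.71% to 11.7% and 17% to 24.1%. These shares separated the deposited sets, and not treated from untreated libraries, since both members of every C70 pair came from the same set. The assignment of C70 within BT474, T47D and ZR75, 3 of the 6 pairs, rests on the file names and could not be checked, because the label of that set describes a mix.

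The first comparison asked what C70 changed in every line. C70 raised 26 genes and lowered 1 across the 6 lines. ZMYND8, a reader of histone marks that can bind KDM5 demethylases (GRCh38 chromosome 20, 47209214 to 47356889), rose by 1.31 ± 0.198 (log2, SE, n = 6 pairs, edgeR adjusted p = 0.0217) and was higher in 6 of 6 lines, from 98.7 to 428 CPM in MCF7, from 84.3 to 384 in FULR and from 104 to 168 in SUM159. KRT15, a keratin of basal progenitor cells (chromosome 17, 41513743 to 41522529), rose by 1.36 ± 0.225 (edgeR adjusted p = 0.0242), from 23.2 to 129 CPM in BT474. The epithelial transcription factor ELF3 (chromosome 1, 202007945 to 202017188) had the smallest p of all genes, with a rise of 0.78 ± 0.0819 (edgeR adjusted p = 0.00369, 6 of 6 lines). In SUM159 it was near the floor, at 1.58 and 2.66 CPM, and 33 genes abundant in the luminal libraries of its set and nearly absent from SUM159 summed to 142 and 469 CPM there. The deubiquitinase gene USP11 (chromosome X, 47232690 to 47248328) rose by 0.90 ± 0.112. BTBD6 (chromosome 14, 105248490 to 105251093) was the gene that fell, by 0.49 on the log2 scale with an SE of 0.0785, and it was lower in 6 of 6 lines. It passed in 9 of 19 alternatives, the fewest of the named genes that were called. The 19 include the fits with all barcodes and with no low-count filter, which equalled the main fit. Every called gene passed in those by construction. No gene was called lower with cells of at most 20% mitochondrial UMIs, or without MCF7, FULR, BT474, T47D or ZR75.

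Further called genes differed in function. IGFBP2, which binds insulin-like growth factors, rose by 0.67 ± 0.0869, the growth factor gene BMP7 by 0.77 ± 0.120 and the neuropeptide precursor VGF by 0.98 ± 0.152. RGS16, a brake on G protein signalling, rose by 1.20 ± 0.209, and LINC00963, a long noncoding RNA, by 1.08 ± 0.191. The transcription factor SOX13 rose by 0.47 ± 0.0755. Each of these had the same sign in 6 of 6 lines, although in SUM159 BMP7 was near the floor, at 2.52 and 3.90 CPM, and open to the luminal transcripts given for ELF3. S100A4 and LGALS1, proteins abundant in mesenchymal cells, rose by 1.43 ± 0.228 and 0.88 ± 0.149 and were higher in 5 of 6 lines. S100A4 went from 105 to 330 CPM in T47D and stayed near the detection limit in FULR, at 3.34 and 2.54 CPM. Its log2 fold was 1.92 within BT474, T47D and ZR75 and 0.71 in the other pairs (edgeR adjusted p = 0.381). S100A4 and LGALS1 passed in 13 and 14 of 19 alternatives. SOX13 and BMP7 passed in fewer, 11 and 12, and ZMYND8 in 14, while USP11 and IGFBP2 passed in 17. The 27 genes came from 7281 tested, 896 had an unadjusted p under 0.05, and DESeq2 called 106 genes, among them all 27.

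KDM5A, KDM5B, KDM5C, ESR1, PGR, GREB1, TFF1 and MKI67 did not pass the test over all genes. KDM5B, the demethylase in the series title (chromosome 1, 202724495 to 202809470), had a log2 fold of 0.27 ± 0.0915 and was higher in 5 of 6 lines (edgeR adjusted p = 0.257); it passed over the 3 genes of the KDM5 list alone. KDM5A had 0.11 (adjusted p = 0.667) and KDM5C −0.09 (adjusted p = 0.764). ESR1, the gene of the estrogen receptor, had −0.19 (adjusted p = 0.662) and its targets PGR, GREB1 and TFF1 had −0.18, −0.32 and −0.17, with adjusted p of 0.843, 0.663 and 0.851. Another estrogen response gene, WISP2, rose by 1.23 ± 0.215 (edgeR adjusted p = 0.0289, 6 of 6 lines), though in FULR it was at 0 and 0.195 CPM. The proliferation marker MKI67 had −0.06 (adjusted p = 0.917).

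The number of called genes depended on which lines were in the fit, while all 27 genes kept their sign in every alternative. It was 9 without MCF7, 8 without FULR, 77 without SUM159, 16 without BT474 and 7 without ZR75. Within the BT474, T47D and ZR75 set edgeR called 1 gene, S100A4, with 830 genes at an unadjusted p under 0.05. ZMYND8 had a log2 fold of 1.02 there (adjusted p = 0.0762) and of 1.65 over the 3 pairs of the other sets (adjusted p = 0.00159), where 28 genes were called. The interaction of C70 with the deposited set reached the threshold for 0 genes by edgeR (305 at an unadjusted p under 0.05, smallest adjusted p 0.0871). With the pairing by line left out of the model, edgeR called 0 genes and 7 had an unadjusted p under 0.05.

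**Figure D1:**
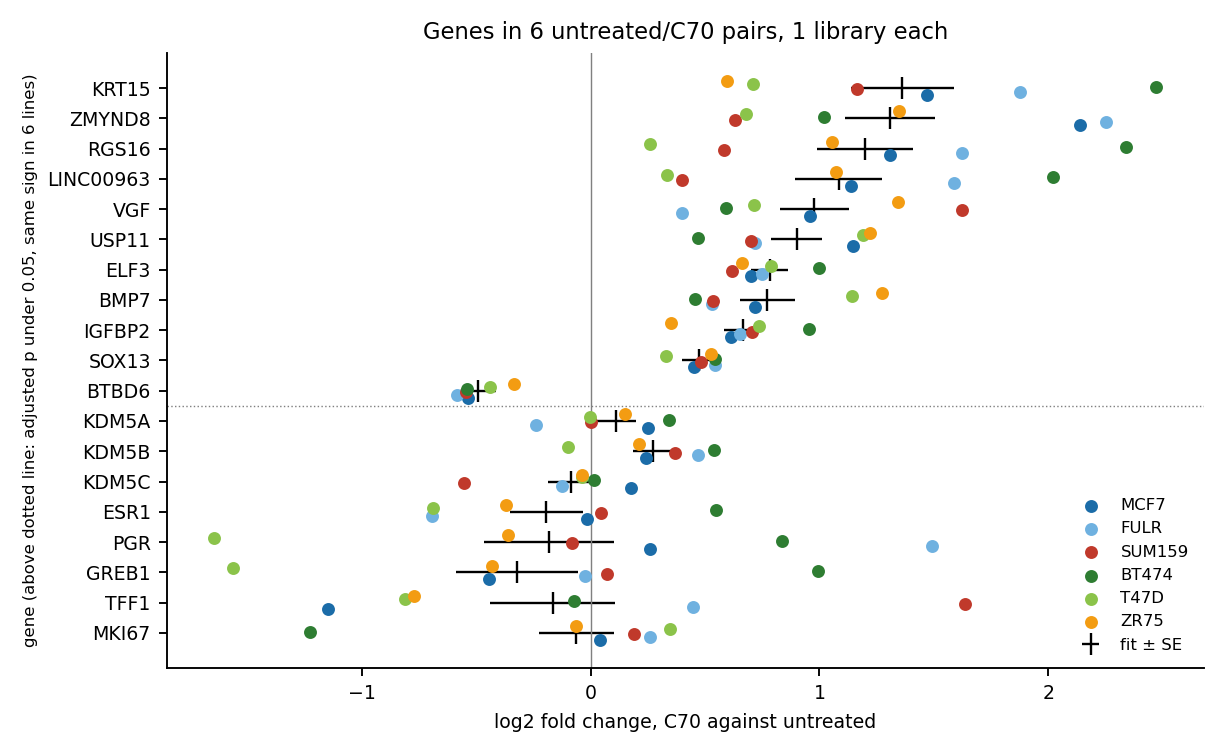
Log2 fold change of C70-treated over untreated cells for each of the 6 lines (points) with the edgeR estimate ± SE, for 11 genes called with 1 sign in all lines and for KDM5A, KDM5B, KDM5C, ESR1, PGR, GREB1, TFF1 and MKI67. ZMYND8 is higher in all 6 lines, BTBD6 is lower in all 6, and the points of PGR, GREB1 and TFF1 lie on both sides of 0.

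Among the gene lists, basal and mesenchymal genes were higher and cell cycle genes lower after C70 than other genes, but no list held once correlation between its genes was estimated. Of the 14 measured basal and mesenchymal genes, 12 had a positive fold, with a median log2 fold of 0.45 (camera adjusted p = 3.65e-05; adjusted p = 0.220 with an estimated correlation). S100A4 and LGALS1 rose, and 8 genes rose with p-values adjusted over the list alone. TGFBI, a secreted matrix protein, had 0.80 and the adhesion receptor CD44 had 0.47, each higher in 6 of 6 lines. FULR counts there only at the floor, with 0 UMIs of both untreated and 0.976 and 1.76 CPM with C70, and its list mean of 0.59 includes these folds. The list mean was positive in 6 of 6 lines, at 0.44 ± 0.23 (SD, exact sign-flip p = 0.03125, the smallest possible, and 0.25 adjusted over lists). Within sets the list median was 0.54 in BT474, T47D and ZR75 and 0.13 in the other pairs. Without the line block the call was lost.

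The ATF4 and unfolded protein response list, genes of amino acid shortage and of stress in the endoplasmic reticulum, had a median of −0.09 and a list mean below 0 in 6 of 6 lines (camera adjusted p = 0.00735; adjusted p = 0.169 with an estimated correlation). Over the list alone 5 of its 19 genes fell and 1 rose. The pseudokinase TRIB3 had −0.58, the serine synthesis enzymes PSAT1 and PHGDH had −0.40 and −0.36, and DDIT4, an inhibitor of mTORC1 signalling, had 0.54. The call was not held without MCF7 (adjusted p = 0.0961) or within the BT474, T47D and ZR75 set (adjusted p = 0.151). Heat shock and immediate early genes had a median of 0.14 over 23 genes (camera adjusted p = 0.00651; adjusted p = 0.169 with an estimated correlation), with DUSP1 at 0.50 and IER2 at 0.33. The list mean was positive in 5 of 6 lines, the median was 0.07 without FULR, and the call was lost without the line block (adjusted p = 0.0771). Mitochondrially encoded genes had a median of 0.11 (adjusted p = 0.0228; adjusted p = 0.220 with an estimated correlation), with the mean positive in 4 of 6 lines. That call was lost without MCF7, without FULR, without ZR75, within either group of sets, with cells of at least 2000 UMIs (adjusted p = 0.0602) and without the line block (0.424).

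The 34 G1/S genes had a median of −0.17 (camera adjusted p = 6.25e-06; adjusted p = 0.390 with an estimated correlation) and the 51 G2/M genes −0.15 (adjusted p = 0.000134; adjusted p = 0.489 with an estimated correlation), with 0 genes of either list called by edgeR and 0 adjusted over the list alone. The list means were negative in 3 of 6 lines for each. BT474 decided both calls: its list means were −0.83 and −0.78, and without it the medians were −0.05 (adjusted p = 0.152) and −0.03 (adjusted p = 0.352). Over the 3 pairs of the other sets the G2/M median was 0.07. Summed over the list, G1/S transcripts went from 1698 to 967 CPM in BT474, and their log2 change over the 6 lines was −0.15 ± 0.36 (SD, exact sign-flip p = 0.4375). G2/M transcripts went from 2655 to 1703 CPM in BT474 and from 5302 to 6854 CPM in SUM159, with a mean change of −0.14 ± 0.36 (exact p = 0.5). Cholesterol synthesis genes had a median of −0.09 (camera adjusted p = 0.0375; adjusted p = 0.390 with an estimated correlation), with the squalene-oxidising enzyme SQLE at −0.33 and FDPS at −0.19. That call was lost without BT474, T47D or ZR75, with cells of at most 20% mitochondrial UMIs (adjusted p = 0.0723) and without the line block (0.818), and the median was 0.03 in the pairs of the other sets.

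The remaining lists did not pass camera. The median was 0.10 for 28 luminal genes (camera adjusted p = 0.0699, 2 genes past the threshold over the list alone) and −0.11 for 12 antigen presentation genes (0.168). Over 16 alternatives the luminal median ran from −0.01 to 0.28 and passed in 5 at the preset correlation. That of antigen presentation ran from −0.30 to −0.0035 and passed in 2. The median was 0.01 for 22 interferon-stimulated genes (0.238) and −0.01 for 35 estrogen response genes (0.765, with a list mean of 0.05). Over the list alone 3 estrogen response genes rose (WISP2, ANXA9 and HSPB8) and 0 fell. HLA-C, a class I antigen-presenting molecule, had −0.41 and was lower in 6 of 6 lines (adjusted p = 0.155; it passed over the list alone). The interferon list mean was positive in 5 of 6 lines, up to 0.77 in ZR75, and −0.86 in FULR. Its median was 0.24 without FULR (camera adjusted p = 1.1e-05), 0.51 within BT474, T47D and ZR75 (1.99e-06) and −0.23 in the other pairs (0.0727), all at the preset correlation. Medians were −0.05 for hypoxia and glycolysis (adjusted p = 0.711, 2 genes higher over the list alone), 0.00 for p53 targets (0.744), 0.03 for oxidative phosphorylation (0.548), 0.01 for ribosomal proteins (0.991) and −0.03 for H3K4 methyltransferases (0.765). The p53 targets BTG2 and CDKN1A, which slow the cell cycle, had 0.50 (adjusted p = 0.0754) and 0.37 and passed over the list alone. In the lists too small to test, ERBB2 had −0.09, the germline gene SYCP2 0.03, the 4 metallothioneins a median of 0.12, and COL1A1, a fibroblast collagen, 0.30. No gene of these small lists passed the test over all genes.

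**Figure D2:**
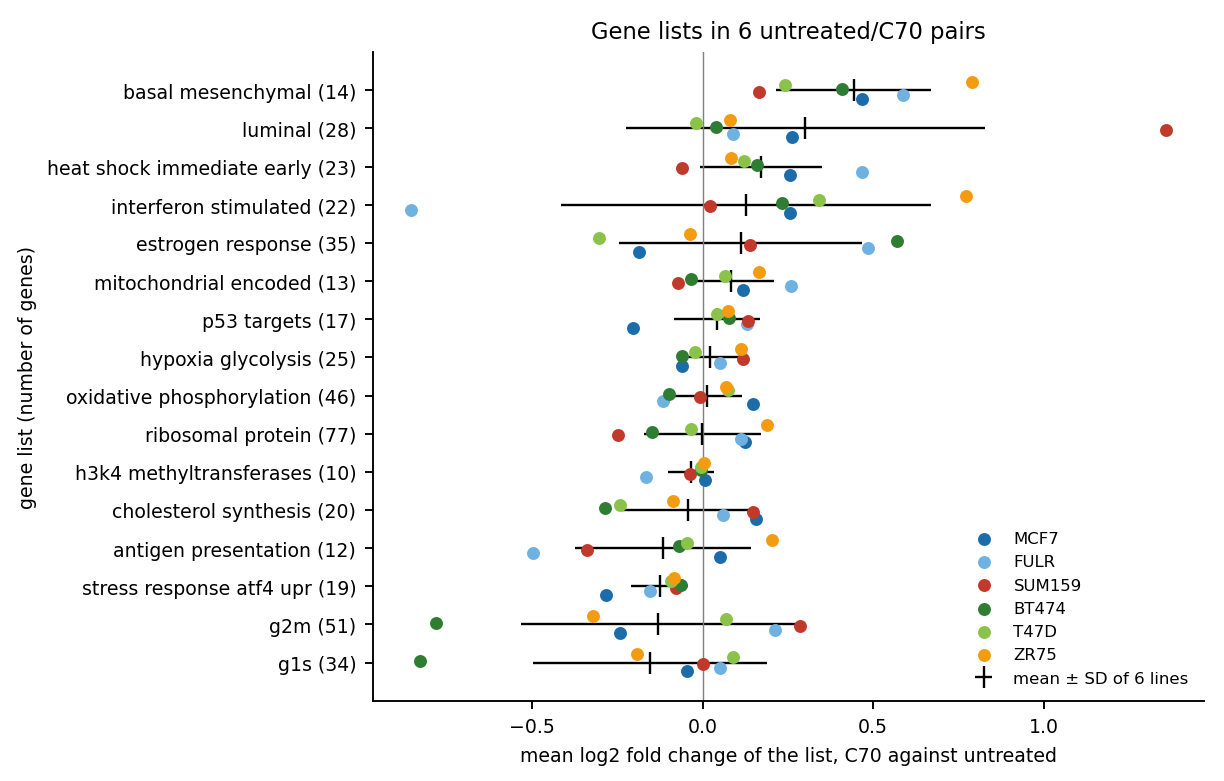
Mean log2 fold change of the genes of each of the 16 tested lists after C70, for each of the 6 lines (points), with the mean over lines ± SD (n = 6). Basal and mesenchymal genes are above 0 in all 6 lines, the ATF4 list is below 0 in all 6, and the G1/S and G2/M means of BT474 (−0.83 and −0.78) lie below those of the other lines.

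Cell-to-cell heterogeneity under C70 did not move in 1 direction. At 1000 UMIs per cell the overdispersion of the median gene went from 0.252 to 0.262 in MCF7, from 0.118 to 0.167 in FULR, from 0.169 to 0.215 in BT474 and from 0.318 to 0.399 in T47D. It went from 0.149 to 0.139 in SUM159 and from 0.347 to 0.292 in ZR75. The mean log2 difference was 0.148 ± 0.292 (SD, n = 6, exact sign-flip p = 0.25), with 0.143 within BT474, T47D and ZR75 and 0.154 in the other pairs. Cells were closer to each other after C70 in 5 of 6 lines by the mean correlation distance, which changed by −0.0107 ± 0.0165 (exact p = 0.1875) and was higher in SUM159, by 0.0169. The within-set means were −0.0128 and −0.00862. With 1 barcode part per line the mean distance was −0.0131, lower in 6 of 6 lines, at the smallest exact p the design allows (0.03125). SUM159 was then near 0, at −0.000307, so that p rests on the sign of this value. At 2000 UMIs per cell the mean distance was −0.00419 (exact p = 0.5625), with 3 of 6 lines lower. Without mitochondrially encoded and ribosomal protein genes the distance was higher in MCF7, by 0.00715. The share of cells with at least 1 ZMYND8 UMI, at 1000 UMIs per cell, was 9.36% in MCF7 (95% interval 7.76% to 11.2%, Clopper-Pearson) and 30.2% in MCF7.C70 (26.8% to 33.6%). No cell type lacking ZMYND8 was measured, so the share due to free RNA is not known.

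The second comparison set C70R, the MCF7 derivative resistant to C70, against MCF7. C70R had higher ZMYND8 and lower estrogen response genes than MCF7. ZMYND8 was at 468 CPM in C70R and 98.0 in MCF7 (ratio 4.77, interval 4.38 to 5.21), and 35.7% of C70R cells had a UMI of it at 1000 UMIs per cell. The sulfate transporter SLC26A2 (chromosome 5, 149960737 to 149993455) was at 101 CPM and 15.7 CPM (ratio 6.40), the iron storage subunit FTL at 1300 and 304 (4.27) and the dehydrogenase DHRS2 at 2838 and 765 (3.71). BAMBI, a decoy receptor of TGF-beta signalling, was at 576 and 196 CPM (2.94), and MUC1, KRT7 and SOX3 were 2.77, 2.45 and 3.04 times higher. KRT81, a hair keratin (chromosome 12, 52285913 to 52291534), was nearly absent, with 2 UMIs in C70R and 229 CPM in MCF7 (ratio 0.00104, interval 0.000125 to 0.00375). CPE had a ratio of 0.0641, the estrogen-induced protease PRSS23 0.129, the matrix proteins FN1 and MGP 0.128 and 0.148, and the EGFR ligand AREG 0.149.

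Of 37 estrogen response genes, 15 were lower in C70R by at least 1.5-fold and 3 were higher, and the median log2 ratio of −0.44 was below all 10000 random lists. STC2, WISP2 and GREB1 had ratios of 0.302, 0.274 and 0.634 and TFF1 0.79, while ESR1 and PGR had 1.02 and 1.13. KDM5B was at 97.7 CPM against 79.5 (ratio 1.23, interval 1.1 to 1.38), KDM5A and KDM5C had 0.84 and 0.817, and MKI67 had 1.28. PGR and MKI67 had log2 ratios of −0.06 and −0.19 when pMCF7 was the control. Interferon-stimulated genes had a median of −0.30 over 26 genes (percentile 1.28), with STAT1 at 0.589 and, going the other way, IFITM1 at 2.87. This list was mixed as well, with 3 genes higher and 4 lower by at least 1.5-fold. Its summed level was higher in C70R, at 7498 CPM against 5794. G1/S genes had −0.29 (percentile 3.34), with PCNA at 0.524, and cholesterol synthesis genes −0.33 (percentile 2.16), with MSMO1 at 0.521. Antigen presentation had −0.34 (percentile 4.22), p53 targets −0.28 (16.5), H3K4 methyltransferases −0.19 (36.5), the KDM5 family −0.25 (46.8) and metallothioneins −0.23 (30.4). Luminal genes had a median of 0.11 (percentile 99.5), with the keratin KRT18 at 1.82, the androgen receptor AR at 2.17 and TFAP2A at 2.04. The 5 basal and mesenchymal genes had 0.54 (above 99.955% of random lists), with LGALS1 at 1.86 and CAV1 at 1.45. The list was mixed, with 2 genes higher and 1 lower by at least 1.5-fold, and its member FN1, given above, went the other way. Oxidative phosphorylation had 0.07 (percentile 98.9, COX6C at 1.89), hypoxia 0.06 (98.4, BNIP3 at 1.58), ribosomal proteins 0.11 (99.7), where oxidative phosphorylation and ribosomal proteins were at −0.03 and −0.17 against pMCF7. Heat shock genes had 0.04 (90.8) and mitochondrially encoded genes 0.05 (71.1).

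With 1 library on each side, these ratios carry counting error only. Ranks among random lists hold neither the spread between cultures nor correlation between the genes of a list. Between pMCF7 and MCF7, both untreated, interferon, antigen presentation and ribosomal protein genes lay above all random lists and G2/M genes at percentile 0.34. As a yardstick, 17 genes were at least 2-fold higher and 34 lower in C70R among 1704 with at least 100 CPM, against 34 and 78 of 1787 between the untreated pMCF7 and MCF7 libraries and 7 and 6 of 1674 between the barcode parts of pMCF7. Between the parts of FULR.C70 there were 20 and 29 of 1598, about as many as in C70R, and between those of SUM159 5 and 18 of 1606 and of fulvestrant-treated pMCF7 4 and 1 of 1539. TMM factors in place of library totals shifted all C70R ratios by 0.16 on the log2 scale. This moved the median of the 1704 genes with at least 100 CPM from −0.08 to 0.07. The G2/M and ATF4 medians, −0.14 (percentile 43.5) and −0.17 (32.2) by library totals, were about the size of that shift.

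Genes that rose with C70 in the other lines were then followed into C70R. The fit without MCF7 called 9 genes, all higher with C70. Their median log2 ratio was 0.59 in MCF7.C70 over MCF7, above all random lists, and 0.13 in C70R over MCF7 (percentile 97.8, random range −0.47 to 0.12). In C70R, MLLT11 was 3.55 times, USP11 1.63 times, IGFBP2 1.36 times, SYNGR3 1.12 times and ELF3 1.09 times the MCF7 level, while the chaperone HSPB8 and the calcium-binding S100A2 had ratios of 0.103 and 0.184, and RASD1 and BTG2 of 0.872 and 0.876. Across 1773 genes the log2 ratios of C70R and of MCF7.C70, both taken over MCF7, had a Pearson r of 0.52 over genes, which are not independent replicates. A shared control with no effect gave the same r of 0.52 in simulations, and r was 0.18 with pMCF7 as the control of C70R. The covariance was 0.0872, against 0.00209 in the simulations, which hold counting noise only, so a deviation of the MCF7 library would enter the excess. Among these genes, which had at least 100 CPM in any of the 3 libraries, 14 were at least 2-fold higher in MCF7.C70 and 17 in C70R, and 6 were shared (0.134 if independent). Of the 9 and 37 lower, 8 were shared (0.188 if independent). Simulated overlaps with no effect were 0 in both directions, and neither value accounts for a deviation of the control.

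The third comparison set fulvestrant-treated against untreated pMCF7, which asks what blocking the estrogen receptor changed. Estrogen response and proliferation genes were lower and immediate early genes higher after fulvestrant. PGR, the progesterone receptor (chromosome 11, 101029624 to 101130524), was at 4.14 CPM against 83.9 (ratio 0.0494, interval 0.0301 to 0.077). GREB1, an estrogen receptor cofactor (chromosome 2, 11482341 to 11642788), was at 106 against 1136 CPM (0.0929), TFF1 (chromosome 21, 42362282 to 42366594) at 1281 against 9900 (0.129) and SIAH2 at 28.8 against 154 (0.187). Of 35 estrogen response genes 29 were lower by at least 1.5-fold and 1 higher, with a median of −1.48, below all 10000 random lists. ESR1 (chromosome 6, 151656691 to 152129619) was at 76.5 CPM against 63.8 (1.20), and KDM5B was at 98.8 against 59.5 (1.66, interval 1.40 to 1.97), while KDM5A and KDM5C had 1.05 and 0.849.

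Cell cycle genes were lower in both phases after fulvestrant. The G1/S median was −1.17, with 24 of 29 genes lower by at least 1.5-fold and 0 higher, and the G2/M median was −0.98, with 36 of 45 lower and 0 higher, both below all 10000 random lists. MKI67 had a ratio of 0.393, the thymidylate enzyme TYMS 0.28, PCNA 0.364 and the mitotic activator CDC20 0.352. The p53 targets as a list had 0.07 (percentile 86.5), but CDKN1A, which inhibits cyclin-dependent kinases, was at 306 against 68.1 CPM (4.49) and BTG2 had 8.2. CTGF, a matrix-associated growth factor (chromosome 6, 131948176 to 131951373), was at 397 against 10.2 CPM (39-fold, interval 27.7 to 56.8), where the untreated MCF7 library held 49.5 CPM; its relative CYR61 had 11.3, the nuclear receptor NR4A1 26.8, FOSB 16.9, DUSP1 10.0 and JUNB 5.98. Heat shock and immediate early genes had a median of 0.54, above all random lists, with 11 of 23 higher and 3 lower. The pMCF7 library was itself low in them, with a median of −0.31 over MCF7 and a DUSP1 ratio of 0.154. Luminal genes had 0.39 (percentile 99.99), with FOXA1, the pioneer factor of luminal cells, at 2.46, ELF3 at 5.52 and CLDN4 at 5.39. The 3 metallothioneins had 1.51 (percentile 99.97), with MT2A at 3.99.

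Interferon, cholesterol and stress response genes were lower too. The interferon list had a median of −1.03 over 27 genes, with 19 lower by at least 1.5-fold and 0 higher; IFITM1 had 0.275 and IFI44L 0.286. The untreated pMCF7 library was itself high in these genes, with a median of 0.87 over MCF7, and against MCF7 the fulvestrant median was −0.11. Antigen presentation genes had −0.53 (percentile 0.54) but 0.39 against MCF7. Cholesterol synthesis genes had −0.76, with ACAT2 at 0.375 and FDFT1 at 0.432, and the ATF4 list −0.66, with the cystine transporter SLC7A11 at 0.247. The 7 basal and mesenchymal genes had −0.80 (percentile 1.75), although FN1 was 4.28 times higher. Hypoxia genes had −0.28 (6.22), oxidative phosphorylation −0.14 (11.8), ribosomal proteins −0.08 (11.8), mitochondrially encoded genes 0.11 (82.4) and H3K4 methyltransferases −0.15 (43.4). In all, 112 of 1697 genes were at least 2-fold higher and 86 lower.

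The fourth comparison set the fulvestrant-resistant FULR, untreated by its label, against pMCF7. Estrogen response genes were lower still than under fulvestrant, and luminal markers were higher. GREB1 was at 5.81 CPM against 1136 (ratio 0.00511, interval 0.00205 to 0.0105), PRSS23 at 19.1 against 1821 (0.0105), the carbonic anhydrase CA12 at 4.98 against 160 (0.031) and TFF1 at 992 against 9900 (0.1). PGR had 0 UMIs in FULR and was at least 33.7-fold lower, and MGP and WISP2, also at 0, were at least 626-fold and 57.4-fold lower. NPY1R had 1 UMI (ratio 0.00506, interval 0.000128 to 0.0283). ESR1 was at 26.5 against 63.8 CPM (0.416, interval 0.277 to 0.606). Of 36 estrogen response genes 34 were lower by at least 1.5-fold and 2 higher, with a median of −3.05. KDM5B had a ratio of 0.99 (interval 0.743 to 1.31), KDM5C 1.14 and MKI67 1.16, and KDM5A was at 33.2 against 26.5 CPM.

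KRT81 had the highest ratio, at 7478 CPM in FULR and 19.7 in pMCF7 (379, interval 296 to 493); the MCF7 library held 229 CPM. The adhesion molecule CEACAM6 was at 243 against 5.55 CPM (43.8), IGFBP5 at 616 against 41.3 (14.9), the membrane substrate of protein kinase C MARCKS had 21.1, CTGF 12.6 (from 10.2 CPM in pMCF7, against 49.5 in MCF7), and RFTN1 was at 136 CPM against 3 UMIs (147, interval 49.5 to 721). Luminal genes had a median of 0.46, above all random lists, with 13 of 27 higher and 2 lower; SPDEF, a factor of secretory epithelium, had 5.37, CLDN4 3.52 and TFAP2A 2.90. Metallothioneins had 1.33 (percentile 99.85), with MT2A at 2.75. The interferon list had −1.24, with 23 of 27 genes lower by at least 1.5-fold and 0 higher, and IFI44L at 0 UMIs (at least 80.6-fold lower); against MCF7 its median was −0.44. Antigen presentation had −0.93, with B2M at 0.253 and HLA-A at 0.316, but 0.13 against MCF7.

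The ATF4 list had −0.69, with DDIT4 at 0.165 and SLC7A11 at 0.172, and hypoxia genes had −0.59, both below all random lists. G2/M genes had −0.33 (percentile 0.07), with 13 of 45 lower by at least 1.5-fold and 1 higher, while G1/S genes had 0.21 (95.7), with 11 of 32 higher and 0 lower; GMNN, a licensing inhibitor of replication, had 2.69 and USP1 2.02. Basal and mesenchymal genes had −0.72 (3.84), cholesterol synthesis 0.21 (92.1), heat shock genes −0.14 (12.9), p53 targets −0.17 (20.9), oxidative phosphorylation 0.06 (67.2), ribosomal proteins −0.05 (28.1), mitochondrially encoded genes 0.04 (62.2) and H3K4 methyltransferases −0.02 (53.5). The germline gene SYCP2 had 3.55. In all, 122 of 1725 genes were at least 2-fold higher and 113 lower. FULR held 502 cells and grew in a medium other than that given for MCF7, with none given for pMCF7 by name. Of its cells 483 came from barcode part 2, while 766 of the 927 pMCF7 cells came from part 1. The ratios of FULR over pMCF7 are therefore not separated from the parts.

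FULR and fulvestrant-treated pMCF7 were then compared, both over the same untreated pMCF7 library. Across 1844 genes with at least 100 CPM in any of the 3 libraries, the log2 ratios had a Pearson r of 0.54 over genes, against 0.42 in simulations with a shared control and no effect. The covariance was 0.429 against 0.00631 in those simulations, which hold counting noise only. With MCF7 as the control of FULR, r was 0.38. Of 131 genes at least 2-fold higher in FULR and 125 after fulvestrant, 50 were shared, against 8.88 if independent and 0.29 simulated with no effect. Of 123 and 91 lower, 44 were shared, against 6.07 and 0.19. A deviation of the single pMCF7 library enters both ratios and is in neither reference value, so the excess is not a measure of a shared effect. CTGF was among those higher in both, and GREB1 and TFF1 among those lower in both.

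**Figure D3:**
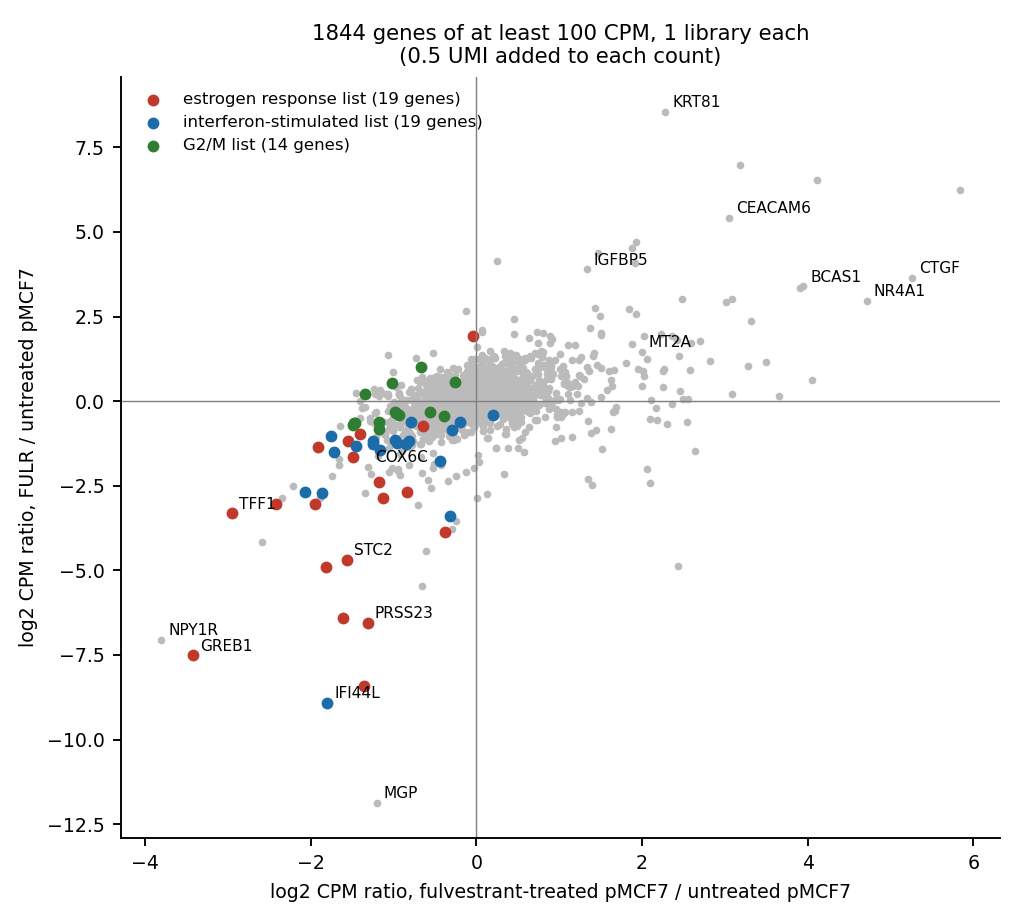
Log2 ratio of FULR over pMCF7 (vertical) against log2 ratio of fulvestrant-treated over untreated pMCF7 (horizontal) for 1844 genes, with 0.5 UMI added, and with estrogen response, interferon and G2/M genes in colour. Estrogen response genes lie low on both axes, and the G2/M list has a median of −0.98 on the horizontal axis and −0.33 on the vertical.

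**Figure D4:**
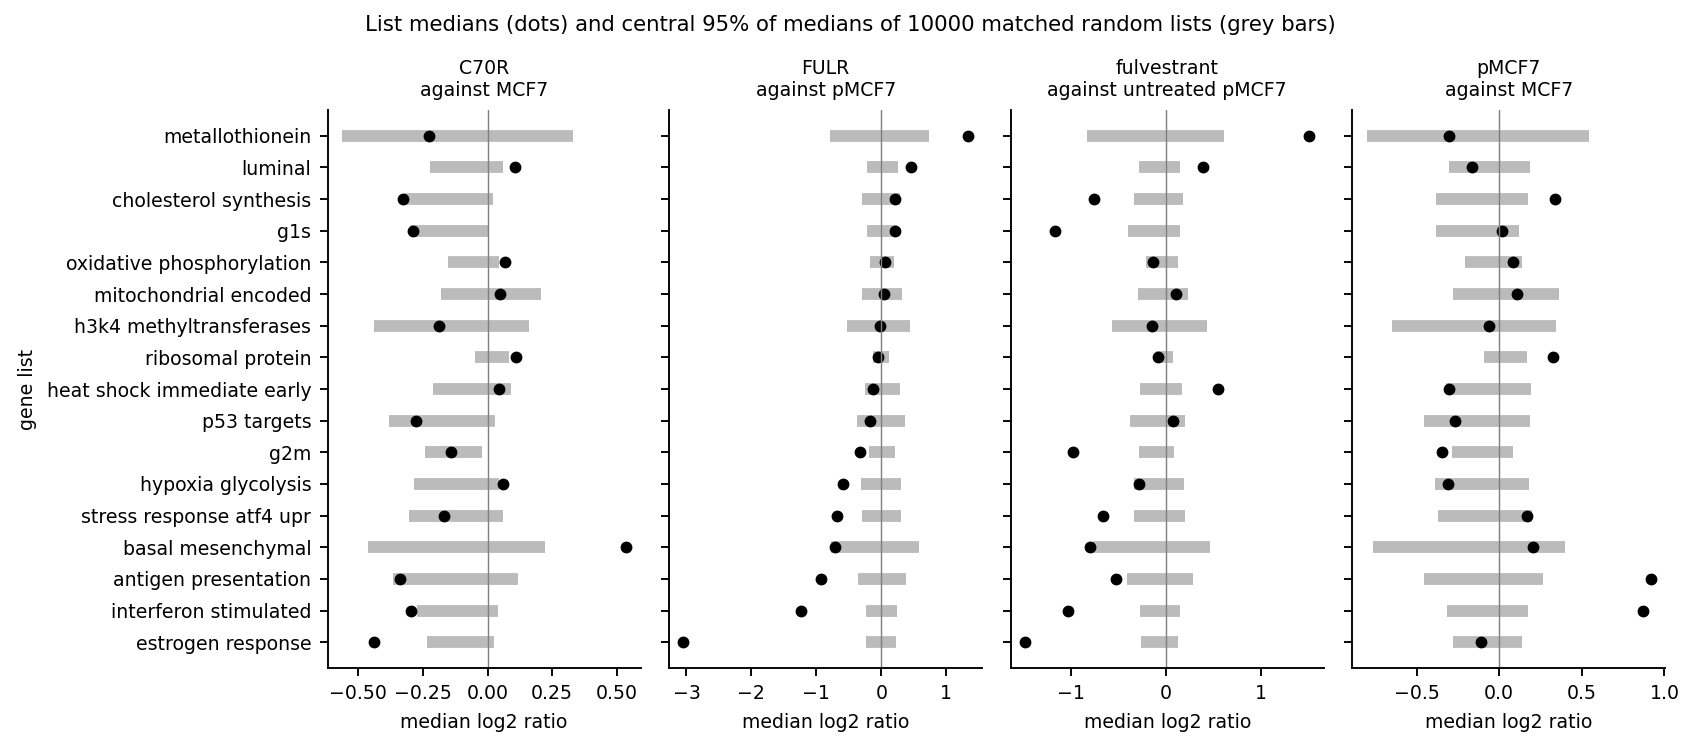
Median log2 ratio of each gene list (points) with the central 95% of 10000 random lists of like expression (grey bars), for C70R over MCF7, FULR over pMCF7, fulvestrant-treated over untreated pMCF7, and pMCF7 over MCF7. Estrogen response genes fall below the bars at −0.44, −3.05 and −1.48, and the interferon list is above its bar at 0.87 in pMCF7 over MCF7.

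The last comparison asked whether resistant or fulvestrant-treated cells differed in heterogeneity. Overdispersion of the median gene was lower in C70R than in MCF7, at 0.175 against 0.230 (log2 ratio −0.39, 95% of resamples −0.58 to −0.27), and lower than in MCF7.C70 (−0.57, −0.73 to −0.45). FULR was lower than pMCF7, at 0.124 against 0.174 (−0.49, −0.87 to −0.29), and fulvestrant-treated pMCF7 was at 0.155 against 0.183 (−0.23, −0.47 to −0.10). Cell-to-cell distances were lower as well, by −0.0457 in C70R, −0.0126 in FULR and −0.0390 with fulvestrant. MCF7.C70 and MCF7 differed by 0.06 (−0.11 to 0.21) in overdispersion and by −0.0148 in distance. The untreated libraries pMCF7 and MCF7 differed by −0.31 (−0.47 to −0.16) and −0.0266, with no treatment on either side. The distance differences in C70R and after fulvestrant were larger than this in every alternative. For overdispersion, and for distance in FULR, the order changed with the settings: at 500 UMIs pMCF7 and MCF7 differed by −0.44 in overdispersion, C70R and MCF7 by −0.41 and FULR and pMCF7 by −0.40. The resamples hold no spread between cultures, and no test was possible.

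**Figure D5:**
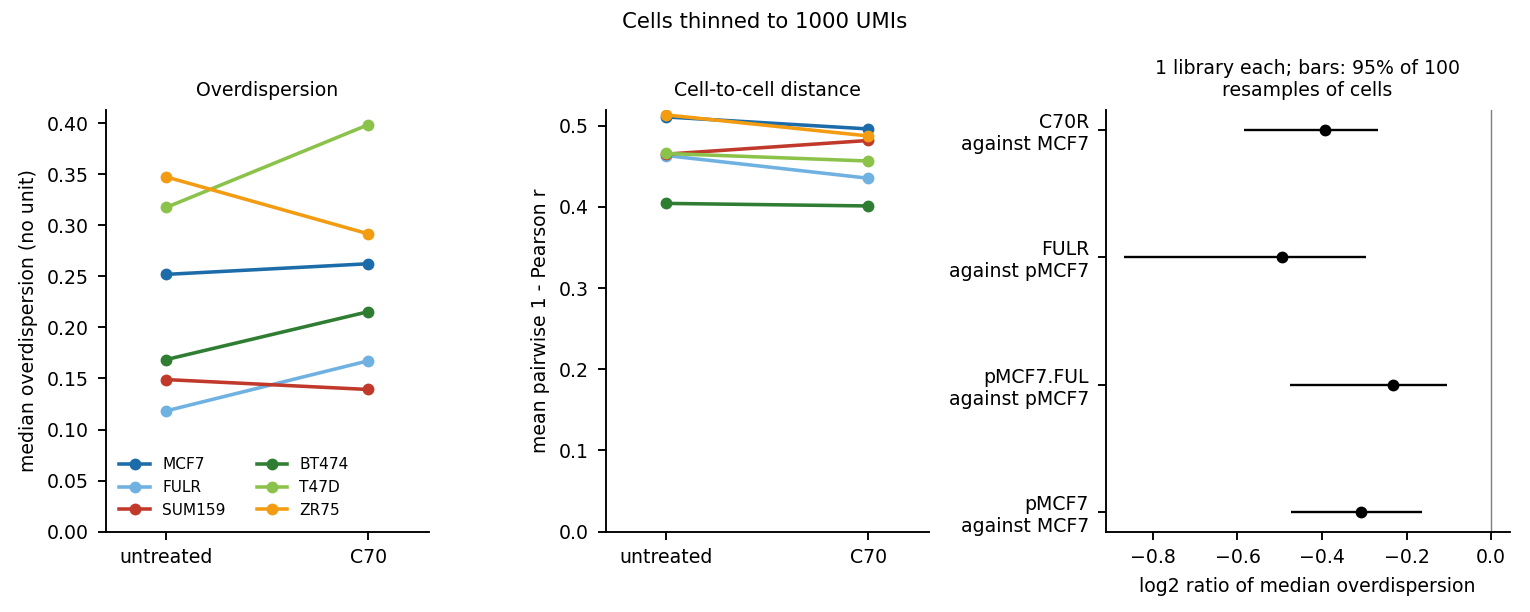
Overdispersion of the median gene and mean cell-to-cell distance at 1000 UMIs per cell for the 6 lines untreated and with C70 (lines join a pair), and log2 ratios of overdispersion with 95% of 100 resamples for comparisons of 1 library with 1. Overdispersion is higher with C70 in 4 of 6 lines, and C70R over MCF7 lies at −0.39.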

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

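The interaction test of C70 with SUM159, the test of RNA from the luminal libraries and the count of splits were chosen only after the result was seen.

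Whether chance could give 27 called genes for C70 was tested by swapping the C70 label within pairs. Of the 32 splits, 1 gave as many genes, the real one, and the highest of the others gave 11. A share of 1 in 32 is the smallest the design allows. The split with 11 called genes had 944 at an unadjusted p under 0.05, more than the 896 with the real labels. The real labels thus stood apart by called genes but not by that count. That split swapped SUM159 alone and kept the real labels in every other pair. An effect of C70 in those pairs would remain in it, so its counts are not those of chance alone. The swaps therefore cannot decide what chance gives by the unadjusted count. MCF7 and FULR are related lines and were swapped as if independent.

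Single lines stood far from the other 5 in 4 of the 34 groups of 6 effects tested, where chance gives about 1.7 (1 in 20). G1/S genes, which serve DNA replication, had a mean log2 fold of −0.83 with C70 in BT474. Luminal genes had 1.36 in SUM159. The p53 targets had −0.20 in MCF7, and H3K4 methyltransferases had −0.17 in FULR.

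The fold with C70 differed between SUM159 and the other 5 lines for 14 genes by the edgeR interaction test, all of them higher in SUM159.C70 relative to the other lines. SUM159 is 1 pair of libraries, so the spread comes from the other 5 lines alone (4 residual degrees of freedom), and the difference need not be an effect of C70. They were CRABP2, MAL2, KRT81, CLDN3, KRT19, TACSTD2, FOXA1, GATA3, CDH1, S100A14, SPTSSB, CEACAM6, S100A2 and MPZL2; the log2 difference was 3.04 for the luminal factor FOXA1, 3.68 for the epithelial adhesion gene CDH1 and 2.62 for the keratin KRT19. These genes were chosen by the test and not by the rule for named genes.

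Luminal genes in SUM159.C70 formed the first pattern weighed: SUM159, a mesenchymal-like line, had more luminal transcripts after C70, and it shared its deposited set with luminal libraries. Luminal genes had a median excess of 1.37% of their level in the luminal libraries. The other genes abundant in those libraries had a median of 1.35% (quartiles 0.759% and 2.04%), so the luminal list was not raised beyond them. That cannot decide whether C70 raised luminal genes in these cells. The other genes were picked by the same rule, as abundant in the luminal libraries and nearly absent from SUM159. RNA of the luminal libraries may account for the pattern: of 33 genes abundant there and nearly absent from SUM159, 93.9% were higher in SUM159.C70, and their summed level went from 142 to 469 CPM (161 to 473 within barcode part 1). Of the 14 genes above, 11 were among these 33. Whether free RNA or a few luminal cells and doublets brought it cannot be told apart. Of the UMIs of the 33 genes, 20.3% lay in the 2% of barcodes that held most of them, between the values set for either. At least 1 was found in 43.4% of SUM159.C70 cells (29.5% in SUM159). The 33 genes were chosen as nearly absent from SUM159, which favours a rise in SUM159.C70. S100A2, of the 14, was not nearly absent there, at 121 CPM in SUM159 and 1152 in SUM159.C70.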

How the results depend on the processing

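The alternatives with 1 barcode part per line, and heterogeneity within sets, were chosen only after the data were seen; all others were planned. Overdispersion under C70 kept its direction in every alternative run, and the C70 genes in C70R kept their direction. The cell cycle sums also did, but no mean of the sums within sets is given, and only 3 lines were lower. Log2 changes of G1/S sums were −0.06, 0.02 and 0.16 in MCF7, FULR and SUM159, and −0.81, 0.10 and −0.32 in BT474, T47D and ZR75. Those of G2/M sums were −0.28, 0.04 and 0.37, and −0.64, 0.02 and −0.34. The fall in the mean is therefore not shown to hold outside the BT474, T47D and ZR75 set. The count of lists that passed camera was 5 to 8 against 7, with changed members, and 0 with an estimated correlation. The number of genes called for C70 was not stable. It was 0 with no line block (the spread between lines then enters the error) and 1 with only the BT474, T47D and ZR75 pairs. It was 60 with 1 barcode part per line, 106 with DESeq2 and 7 to 77 with each line left out. It was 23 to 30 in the other 9 alternatives, and all 27 genes kept their sign in every one, but 14 of the 29 called with thinned UMIs and 12 of the 28 called in the pairs of the other sets were among the 27. The results for named genes were the same in 1503 cases, passed the threshold that had not in 16 and no longer passed in 72. Keeping all barcodes and applying no low-count filter changed nothing, since neither filter removed anything, and say nothing of stability.

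Of the lists that had passed, those that turned direction were the basal and mesenchymal list without the line block (camera pointed down while the median was 0.20), and in the pairs of the other sets cholesterol synthesis (0.0264) and G2/M (0.0656), both of which camera placed up. Lists that had not passed also changed sign: the interferon median of 0.01 was −0.07 without the line block (camera adjusted p = 0.00203) and −0.23 in the pairs of the other sets. Of the other list results, 223 were the same, 12 passed the threshold that had not and 18 no longer passed. The cell-to-cell distance under C70 was −0.0131 with 1 barcode part per line, at the smallest p possible but with SUM159 near 0 (−0.000307). It was negative in the other 19 alternatives. With a line left out, or within sets, the 5 or 3 pairs could not bring the sign-flip p under 0.05, so missing the threshold there says nothing of stability. In the unreplicated heterogeneity, 3 of 36 values moved beyond their resamples: overdispersion after fulvestrant to −0.51 without cells above 3 times the median UMIs, distance after fulvestrant to −0.0549 at 500 UMIs, and distance of pMCF7 from MCF7 to −0.0109 at 500 UMIs. For the 1-library comparisons the control mattered most among the alternatives run. The genes at least 2-fold apart numbered 197 for C70R against pMCF7 in place of MCF7, and 433 for FULR and 356 for fulvestrant against MCF7 in place of pMCF7.

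TMM factors moved the C70R G2/M median from −0.14 to 0.0157 and the fulvestrant ribosomal median from −0.08 to 0.0127; neither had lain outside the range of random lists. Values that had stood apart changed sign with the control library only. C70R against pMCF7 had log2 ratios of −0.0323 for oxidative phosphorylation, −0.17 for ribosomal proteins, −0.0877 for ALDOA, 0.94 for CCNG1, 0.19 for CEBPB, 0.0556 for DPY30, 0.34 for ECT2, 0.41 for GDF15, −0.19 for MKI67 and −0.0615 for PGR. FULR against MCF7 had 0.13 for antigen presentation, −0.32 for CAV1, −0.33 for DUSP1 and −0.42 for ZFP36. Fulvestrant against MCF7 had 0.39 for antigen presentation and for TAP2, −0.64 for CAV1, −0.22 for CAV2, −0.34 for DNAJB9, 0.25 for HLA-A, 0.21 for HLA-C, 0.0517 for IFIT3 and 0.0762 for TAP1. Without a sign change, 124 values of C70R, 54 of FULR and 62 after fulvestrant moved beyond their counting intervals, and 381, 452 and 414 did not. The cause was not tested for these, for the pairs or lines left out, for the barcode parts, for DESeq2 or for the moved heterogeneity. FULR, at 1205483 UMIs, limits what can be seen there, since a gene at 0 UMIs is bounded only by the floor of 2.49 CPM (3 counts).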

Other observations

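The VIM test against SUM159 and both tests of the interferon list against MCF7 were chosen only after the result was seen, and so were the single-line ratios of the next paragraphs.

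Large ratios with C70 in single lines are given here between 1 library and 1, with no test of the ratio or, for these genes outside SUM159, of a difference between lines. In BT474.C70 the mTOR inhibitor DEPTOR was at 110 CPM against 22.9 and GPNMB, a glycoprotein of lysosomes, at 296 against 72.9, while the replication enzymes TYMS and RRM2 had ratios of 0.382 and 0.465. In ZR75.C70 the iron and heme genes FTL and HMOX1 were at 783 against 260 and 320 against 126 CPM, and the secretory breast protein SCGB2A2 at 733 against 3139. T47D.C70 had PGR at 33.5 against 106 CPM and GREB1 at 43.6 against 130, both estrogen receptor targets. BT474.C70 had both higher, with PGR at 351 against 197 CPM and GREB1 at 160 against 80.6. T47D.C70 also had ID1 at 272 against 88.1 CPM and the fatty acid transporter CD36 at 259 against 120.

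FULR.C70 held more immediate early and fewer interferon transcripts than FULR, with NR4A1 at 314 against 63.0 CPM, EGR1 at 912 against 265, IFITM1 at 60.1 against 203 and ISG15 at 117 against 287. FULR lay almost wholly in barcode part 2 (483 of 502 cells) and FULR.C70 in both, and the parts of FULR.C70 differed at least 2-fold in more genes (20 higher, 29 lower) than FULR.C70 did from FULR (17 and 10), so these ratios are not separated from the parts. KRT81, high in FULR, was at 3458 against 7478 CPM. KRT7, a simple epithelial keratin, was higher with C70 in MCF7 (143 against 43.0 CPM), FULR (643 against 171) and ZR75 (176 against 32.5). SUM159.C70 lay almost wholly in barcode part 1 (1650 of 1676 cells) and SUM159 in both (1309 and 967), whose parts differed at least 2-fold in more genes (5 higher, 18 lower) than SUM159.C70 did from SUM159 (4 and 0). In SUM159.C70 the calcium-binding S100A2 was at 1152 against 121 CPM, and HLA-A and HLA-B had ratios of 0.65 and 0.636.

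Across 2571 genes the C70 folds of MCF7 and ZR75 had a Pearson r of 0.43, those of T47D and ZR75 0.32 and those of MCF7 and FULR 0.25. Folds of SUM159 had r of −0.03 to 0.05 with the other 5 lines. Genes are not independent replicates, and the 6 lines came from 3 deposited sets.

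More BT474 cells held VIM, a mesenchymal filament gene, after C70, at 8.94% against 1.63% of cells with 1000 UMIs each (98.4 against 15.6 CPM). In the same set the share was 0.188% against 0.427% in ZR75 and 1.40% against 0.791% in T47D. The tables argue against a difference in depth, since the ratio at equal UMIs was 5.49, and against RNA or cells of SUM159, since 6.25% of 16 genes abundant in SUM159 (1 gene) rose as VIM would need. A response of some BT474 cells to C70 may be involved, but with 1 library per condition a difference between cultures cannot be excluded, and no test of it could be run.

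Interferon-stimulated genes were lower in FULR and after fulvestrant than in pMCF7, whose library was high in them. A high control library may account for this: against MCF7 the median after fulvestrant was −0.11, inside the range of random lists (−0.51 to 0.16), with 15 of 27 genes lower. For FULR it was −0.44, inside the range (−0.49 to 0.30) but near its edge (percentile 4.41), with 20 of 27 genes lower. Whether the barcode parts contributed after fulvestrant cannot be told apart, because the median was −0.48 within part 2, between the values set for either outcome. Both parts showed a fall, and −1.32 within part 1 was past the value set against the parts. For FULR no median within a part was taken. In FULR 483 of 502 cells lay in part 2, against 161 of 927 in pMCF7, so a contribution of the parts stays open there. An effect of fulvestrant on these genes stays open, since MCF7 comes from another set and differs from pMCF7 in more than these genes.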
